A study of Mus musculus with 6 samples.

How the data were processed

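Hippocampi of 3 wildtype and 3 miR-17-92 knockout mice aged 13 weeks were dissected and total RNA was purified on silica columns with a DNase step, per the labels' protocols. The authors deposited raw read counts per gene, 1 table per mouse, with 37620 Ensembl gene identifiers each. Per the submitters' processing notes, FastQC 0.10.1, STAR 2.3.0e, SAMtools, HTSeq and DESeq2 were used with genome build mm9. The role of each tool, the annotation and the strand setting are not given in the sources used here, so reads of overlapping and antisense genes cannot be told apart. The 5 closing rows of each table name no gene (reads in no feature, ambiguous, of low quality, not aligned, or placed at several sites). They held 38.0% to 40.3% of each file's total and were left out of library sizes and tests.

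Gene names, gene order along chromosomes, transcript sequences and 3' UTRs came from GENCODE M21 on GRCm38. The reads were counted on mm9, so no coordinates are given. Of the 37620 identifiers 32897 matched a name. Gene counts per library ran from 26439693 to 57246827. Values per gene are CPM with TMM library sizes unless each library is listed, where they are CPM of the gene total. Limits for a count of 0 cover counting error only.

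The main test was the quasi-likelihood test of edgeR 4.0.16 (R 4.3.3) on genotype alone, with filterByExpr, TMM factors and Benjamini-Hochberg adjustment at 0.05. The mice came from different litters, so replicate numbers pair nothing. There were 31 gene lists with 598 entries, of which 595 matched. Of these 29 were tested with camera (limma 3.58.1) at a preset correlation of 0.01 and again with an estimated correlation and with fry. None of the 8 lists that passed did so with an estimated correlation or with fry's directional test. Fry's mixed test, which takes changes of members in either direction together, gave glucocorticoid, immediate early and astrocyte lists adjusted p of 0.0110, 0.0193 and 0.00169. Oligodendrocytes and cortex had 0.412 and 0.179 in it. Lists that camera did not pass were also under 0.05 in it, such as neural stem cells (0.0129), cluster targets (0.0144) and anxiety and depression (0.00185). The lists covered the study's questions (neural stem cells, proliferation, newborn neurons, glucocorticoid response, reported cluster targets), cell types, neighbouring tissues, cell states and RNA quality. Seed sites were 7 bases long, searched in each gene's longest 3' UTR, and tested as 5 sets among genes with a 3' UTR. List and seed folds are knockout over wildtype.

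Design, lists, the settings to be tried and the rule for naming genes were fixed before the data were examined. The lists on the study's questions drew on the series title and on what is known of the study, so they may not be independent of its findings. Named genes were the cluster host, Sgk1, Sgk3, Nr3c1, Fkbp5, Tsc22d3, Dcx, Nes, Mki67 and Eomes, up to 3 members with the smallest p of each list described, and, since fewer than 6 genes passed in either direction with edgeR, the 8 genes with the smallest p per direction. Of the genes this rule takes, 2 are not reported here. Under this rule predicted genes, pseudogenes and identifiers without a symbol were counted but not named. Other genes, the pseudogene Vcp-rs among them, were chosen after their values were seen, and are said to be.

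The settings tried, all chosen beforehand, were DESeq2 size factors, upper quartile factors, no filter beyond 1 read, a filter of 1 CPM in 3 libraries, DESeq2 1.42.0, limma-voom, edgeR's robust fit, a replicate block, an adjusted p of 0.10, other list tests, other seed definitions, and leaving out each library. Added after the data were seen were offsets for GC content and transcript length, counts thinned to the smallest library, bias-adjusted deviances, the depth set as a covariate, and leaving out chromosome 17. The depth sets are the 3 libraries with more and the 3 with fewer gene counts than the median. They are not groups of the study, and were looked at after that split of the libraries had called the most genes of the 10 splits with edgeR. The same split had first been tried by the level of 1 gene, with the same libraries on each side. The deeper set holds knockout replicate 3 alone of its genotype, and the shallower set wildtype replicate 3 alone of its own.

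The scripts were tested on simulated counts with 200 changed genes among 16265 tested. For knockout against wildtype edgeR recovered 42% of genes changed 1.25-fold, 82% at 1.5-fold, 96% at 2-fold and 98% at 3-fold, with 14 false calls among 173. DESeq2 made 29 false calls among 193. These shares of false calls are above the nominal level, more so for DESeq2. Counts were drawn once, from the dispersions that edgeR estimated in these libraries, so recovery in the data may be lower. Hif3a, at a fold of 2.04 in the data, had an adjusted p of 0.0624 with edgeR. The comparison of the tools holds for such simulated counts only. Both lists shifted by 0.15 and -0.25 on the log2 scale were called with no other list. Simulated genes varied independently of each other, so this does not test the preset correlation on lists whose members vary together. A planted seed effect of 0.05 lay at percentile 100 of shuffled motifs, and a planted window of neighbouring genes was found.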

Results

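Gene expression was measured by RNA sequencing in the hippocampus of 13-week-old C57BL/6 mice, 3 wildtype and 3 labelled as knockouts of the miR-17-92 cluster, a group of microRNAs transcribed together from the host gene Mir17hg. No litter gave more than 1 mouse. The series concerns the part of this cluster in adult hippocampal neurogenesis, anxiety and depression, so 1 comparison was made, knockout against wildtype. Reads assigned to genes came to 40100762, 43588323 and 31731263 in wildtype replicates 1, 2 and 3, and to 32284831, 26439693 and 57246827 in knockout replicates 1, 2 and 3. Xist lay between 1328 and 1491 CPM (reads per gene scaled to library size) in the 6 libraries, and the Y-linked genes Ddx3y, Uty, Eif2s3y and Kdm5d held at most 1 read in any of them.

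The host transcript Mir17hg (ENSMUSG00000089726, chromosome 14) was read at a low level in both genotypes. Wildtype libraries held 43, 47 and 36 reads and knockout libraries 30, 35 and 37, which is 1.09 ± 0.033 CPM in wildtype and 0.970 ± 0.34 CPM in knockout (SD, n = 3). The log2 fold of -0.22 (SE 0.28) did not pass in edgeR's quasi-likelihood test (adjusted p = 0.813), and it turned to 0.04 without knockout replicate 3. The 6 microRNA hairpins of the cluster had 0 reads in every library, where a count of 0 allows up to 3. With 0 reads in wildtype too, the hairpin counts could not show a loss in knockout. The labels do not state which part of the gene was removed or in which cells, so these counts neither check the genotype labels nor go against them.

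No single gene passed the threshold in the main test. Of 16432 genes tested with edgeR, 0 had an adjusted p under 0.05, and the smallest was 0.0624. At an unadjusted p under 0.05 there were 1746 genes, 829 higher and 917 lower in knockout, where chance gives 822. DESeq2 called 163 genes (70 higher, 93 lower), limma-voom 0 and edgeR's robust fit 15. Knockout and wildtype libraries did not overlap for 2733 genes, 16.6% of those tested, where chance gives 10%.

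None of the genes with the smallest p values passed in the main edgeR test. Gjb6, a gap junction protein of astrocytes, measured 39.2 ± 2.2 CPM in wildtype and 58.3 ± 3.6 CPM in knockout (SD, n = 3), a log2 fold of 0.58 (SE 0.06). Zbtb16, a transcription factor induced by glucocorticoids, had a log2 fold of 0.44 (SE 0.06), and Calb1, the calcium-binding protein calbindin of dentate granule cells, one of 0.46 (SE 0.06). Hif3a stood at 6.31 ± 1.2 CPM against 12.9 ± 1.0 CPM, a log2 fold of 1.03 (SE 0.13). Log2 folds of Mut (methylmalonyl-CoA mutase), Selenop (the selenium carrier selenoprotein P) and Rin2 were 0.46, 0.44 and 0.38. On the lower side, log2 folds were -0.33 for Actb, -0.29 for Zkscan1, -0.32 for Ephb3, -0.35 for Tet1 and -0.52 for Plekho2. Values of H2-D1 (0.65), H2-T24 (-0.69) and Rps2 (-0.79) are uncertain, because these genes belong to families with close relatives or pseudogenes among which the counting could split reads, as does Actb. Read sharing was not measured for them. Mut, H2-D1, H2-T24 and Rps2 lie on chromosome 17, where genes of small p lay together, as described below. The adjusted p of these 16 genes lay between 0.0624 and 0.118 in the main edgeR test, the highest being Nr4a1, Ephb3, Tet1 and Plekho2. With edgeR's robust fit Gjb6, Mut, Zbtb16, Calb1, H2-D1, Hif3a, Selenop, Rin2, H2-T24 and Rps2 passed (adjusted p of 0.0249 to 0.0363). All 16 passed with DESeq2, which made more false calls in the simulation.

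Genes of the glucocorticoid response rose in the knockout hippocampus as a list. Of 29 tested members 21 had a positive fold, with a mean log2 fold of 0.13 (SE across genes 0.05) and a camera adjusted p of 2.85e-06 over 29 lists. This became adjusted p = 0.421 with an estimated correlation. Adjusted over the list alone, 10 members were higher and 2 lower with edgeR, against 0 over all genes tested with edgeR and 5 higher and 1 lower with DESeq2. Sgk1, a kinase induced by glucocorticoids, measured 72.8 ± 2.9 CPM in wildtype and 97.2 ± 16 CPM in knockout (SD, n = 3), a log2 fold of 0.42 (SE 0.10, adjusted p = 0.286), or 0.28 without knockout replicate 3. Fkbp5, a co-chaperone that dampens the glucocorticoid receptor, had a log2 fold of 0.28 (SE 0.07), Tsc22d3 one of 0.39 (SE 0.14), or 0.19 without knockout replicate 3, and Mertk one of 0.31 (SE 0.05). The receptor gene Nr3c1 itself had a log2 fold of -0.14 (SE 0.05), and Sgk3 one of -0.04 (SE 0.11). The genotypes overlapped in the list's level, with knockout replicate 2 at -0.02 and wildtype replicate 2 at -0.01 relative to the mean of the 6 libraries. The list's mean log2 fold was 0.05 without knockout replicate 3 and 0.06 without wildtype replicate 1. Both were past the threshold only for camera at the preset correlation of 0.01, where the correlation estimated for this list was 0.20. Within the 3 deeper libraries (wildtype 1 and 2, knockout 3) the list's level was 0.26 higher in knockout, and within the 3 shallower ones 0.05 higher, on the log2 scale. Knockout replicate 3 was also the highest library in the heat shock list, at 0.41 against -0.30 and -0.15 in knockout replicates 1 and 2, and knockout minus wildtype in that list was 0.42 within the deeper and -0.27 within the shallower libraries.

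**Figure D1:**
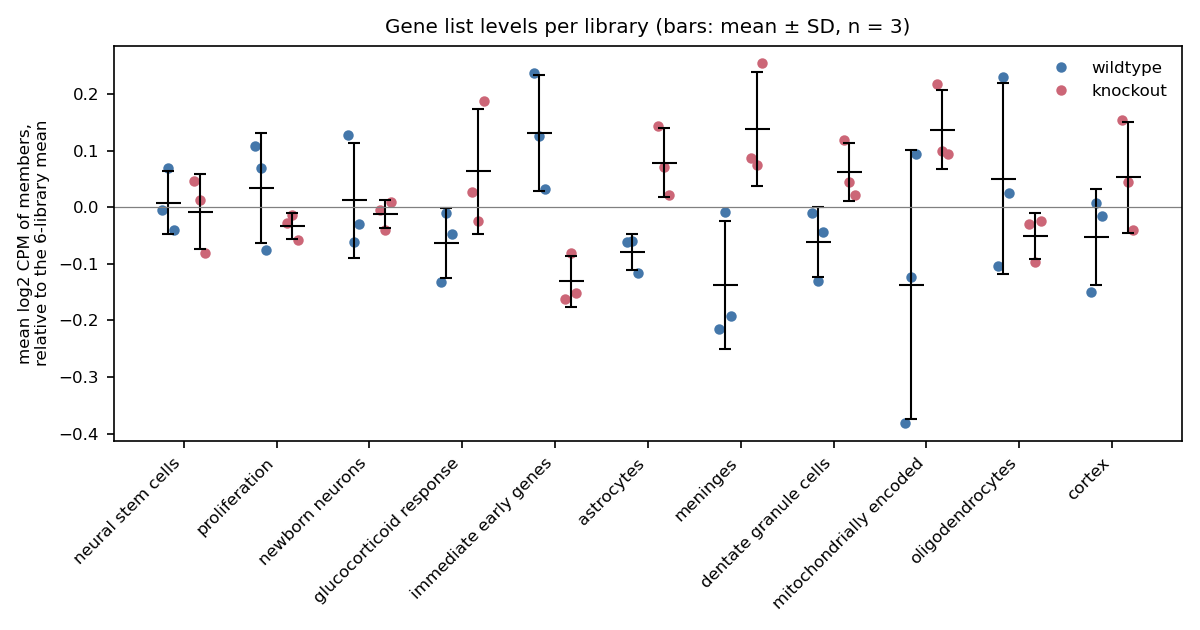
Level of 11 fixed gene lists in each library, as the mean log2 CPM of the members relative to the mean of the 6 libraries (vertical axis); points are libraries, and bars give the mean ± SD of the 3 per genotype. The wildtype and knockout points do not overlap for immediate early genes, astrocytes, meninges and dentate granule cells.

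Immediate early genes, which neurons switch on within minutes of firing, fell in knockout as a list. Of 20 members 15 had a negative fold, the mean log2 fold was -0.27 (SE across genes 0.07), and the camera adjusted p was 6.73e-12, or adjusted p = 0.204 with an estimated correlation. Adjusted over the list alone, 11 were lower and 2 higher with edgeR, against 0 over all genes tested with edgeR and 10 lower and 0 higher with DESeq2. Arc, a protein of active synapses, measured 385 ± 44 CPM in wildtype and 263 ± 31 CPM in knockout (SD, n = 3), a log2 fold of -0.55 (SE 0.10). Egr2 and Nr4a1 had log2 folds of -0.70 (SE 0.12) and -0.47 (SE 0.07). Knockout minus wildtype in the list's level was -0.33 within the deeper libraries and -0.15 within the shallower ones.

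Astrocyte markers rose in knockout as a list, with 18 of 20 members at a positive fold, a mean log2 fold of 0.16 (SE across genes 0.04) and a camera adjusted p of 6.73e-12, or adjusted p = 0.204 with an estimated correlation. When adjusted over the list alone 6 were higher and 0 lower with edgeR, among them Gjb6, against 0 over all genes tested with edgeR and 4 higher with DESeq2. Fam107a went from 265 ± 19 to 352 ± 12 CPM (SD, n = 3), and the bicarbonate transporter Slc4a4 had a log2 fold of 0.19 (SE 0.04). Within the deeper and the shallower libraries the list's level was higher in knockout by 0.08 and 0.22.

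Among neuron types, markers of dentate granule cells rose as a list (14 of 18 positive, mean log2 fold 0.12, camera adjusted p = 8.53e-06, or adjusted p = 0.204 with an estimated correlation). Calb1, Pter (log2 fold 0.40, SE 0.05) and the melanocortin receptor Mc4r (0.62, SE 0.12) had the smallest p. Of these genes, adjusted over the list alone, 3 were higher and 0 lower with edgeR, against 0 over all genes tested with edgeR and 3 higher with DESeq2. Lists for CA1 pyramidal cells, CA2 and CA3 pyramidal cells and GABAergic interneurons did not pass (camera adjusted p of 0.493, 0.887 and 0.848). Within the deeper and the shallower libraries the dentate level was higher in knockout by 0.09 and 0.13. The genotypes did not overlap in the dentate, astrocyte, immediate early and meningeal lists. The signs within each depth set were therefore fixed for these lists and add no support.

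Genes of the adult neurogenic lineage did not shift as lists. Neural stem cell genes had 10 of 20 members higher and 10 lower (camera adjusted p = 0.887), proliferation genes 8 of 25 higher and 17 lower (0.383), and newborn neuron genes 10 of 20 higher and 10 lower (0.887). Dcx, a microtubule protein of newborn neurons, measured 42.5 ± 4.7 CPM in wildtype and 37.0 ± 0.77 CPM in knockout (SD, n = 3), a log2 fold of -0.20 (SE 0.08, adjusted p = 0.424). Eomes, a marker of intermediate progenitors, was near the floor at 0.800 ± 0.29 and 0.503 ± 0.13 CPM, a log2 fold of -0.70 (SE 0.34). Adjusted over the list alone 2 neural stem cell members were lower and 0 higher, Notch1 (log2 fold -0.38, SE 0.08) and Sox9 (-0.33, SE 0.08), against 0 over all genes tested with edgeR and both with DESeq2, while Id4 stood at 0.22. Mki67 and Nes had log2 folds of -0.07 (SE 0.18) and -0.01 (SE 0.14), and Sox4 and Elavl2 of -0.24 and 0.12. Ccnb2, Ccne2 and Cenpe had log2 folds of -0.46, 0.25 and -0.20, where Ccne2 was 0.15 without wildtype replicate 3 or without knockout replicate 2, and Cenpe -0.12 without knockout replicate 2. These genes are read in few cells of a whole hippocampus, and changes confined to those cells were not detectable here unless they moved the tissue level.

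**Figure D2:**
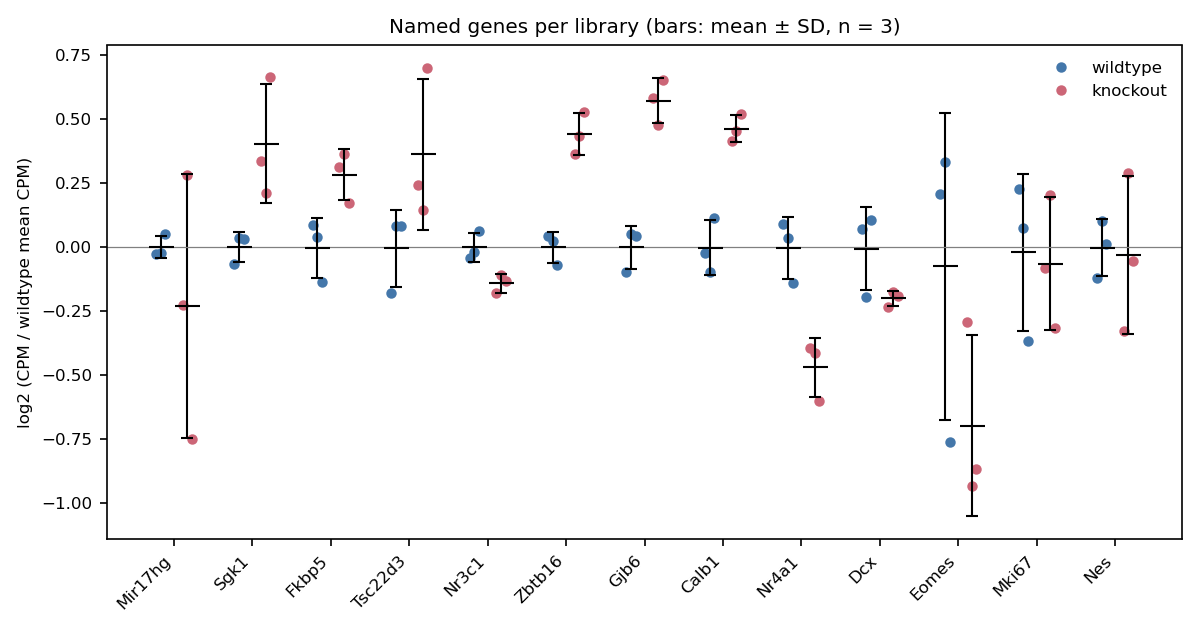
Level of 13 named genes in each library as log2 of CPM over the wildtype mean (vertical axis); points are libraries, and bars give the mean ± SD of the 3 per genotype. Gjb6 lies 0.58 and Nr4a1 -0.47 from wildtype on the fitted log2 scale, while the Mir17hg libraries of both genotypes overlap.

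Reported targets of the cluster did not shift as a list, with 16 of 35 members higher and 19 lower, a mean log2 fold of -0.01 and a camera adjusted p of 0.887. Ccnd1, which encodes cyclin D1, had a log2 fold of -0.42 (SE 0.09). Adjusted over the list alone 1 member was higher and 1 lower with edgeR, against 0 over all genes tested with edgeR and 1 higher and 1 lower with DESeq2. The higher one was Sgk1, which also counts in the glucocorticoid list, and the lower one was Ccnd1. Of 14542 tested genes with an annotated 3' UTR, 2164 held a seed site of miR-17, 1488 of miR-18, 2002 of miR-19 and 1160 of miR-92. Mean log2 folds of these sets were 0.01, -0.003, 0.01 and 0.01, and none passed (camera adjusted p of 0.428 or more). These are values of the whole tissue, and a deletion limited to some cells would move them less than one in all cells.

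Other tissue and quality lists moved as well. Meningeal genes rose (18 of 20 positive, mean log2 fold 0.27, camera adjusted p = 2.85e-06, or adjusted p = 0.240 with an estimated correlation), with Ptgds at 174 ± 23 and 267 ± 54 CPM (SD, n = 3) and log2 folds of 0.76 for Slc13a4 and 0.71 for Ogn. Mitochondrially encoded transcripts rose (10 of 12 positive, mean 0.25, adjusted p = 2.19e-05, or adjusted p = 0.421 with an estimated correlation), with log2 folds of 0.25 for mt-Nd2, 0.18 for mt-Nd4 and 0.22 for mt-Nd1. The mean of that list was 0.09 with a filter of 1 CPM in 3 libraries, 0.15 without wildtype replicate 1 and 0.51 without wildtype replicate 3. Oligodendrocyte genes fell (19 of 24 negative, mean -0.11, adjusted p = 0.00757, or adjusted p = 0.721 with an estimated correlation), with Mag at -0.26 and Mbp at -0.15. The oligodendrocyte mean was -0.18 without wildtype replicate 1. Without wildtype replicate 2 it was -0.01 (adjusted p = 0.947), with Mag at -0.15 and Mbp at -0.07, and without knockout replicate 2 it was -0.08 (adjusted p = 0.0689), with Mbp at -0.09. With the depth set as a covariate it was -0.09 (adjusted p = 0.0763). Cortex genes rose (16 of 20 positive, mean 0.09, adjusted p = 0.0457, or adjusted p = 0.710 with an estimated correlation), with Etv1 at 0.23, Lamp5 at 0.15 and Pcp4 at 0.14. The cortex mean was 0.05 without wildtype replicate 1 (adjusted p = 0.240), 0.14 without wildtype replicate 2 (adjusted p = 0.0514), 0.04 without knockout replicate 1 (adjusted p = 0.249) and 0.06 with the depth set as a covariate (adjusted p = 0.120), and its adjusted p was 0.0716 with limma-voom and 0.0534 with a filter of 1 CPM in 3 libraries. Within the deeper and the shallower libraries, knockout minus wildtype was 0.37 and 0.27 for meninges, 0.35 and 0.06 for mitochondrial transcripts, -0.09 and -0.09 for oligodendrocytes, and 0.03 and 0.12 for cortex.

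Genes tied to anxiety and depression did not pass as a list (15 of 24 positive, camera adjusted p = 0.323), with log2 folds of 0.37 (SE 0.08) for the GABA receptor subunit Gabra2, 0.17 (SE 0.06) for Bdnf and 0.11 (SE 0.04) for its receptor Ntrk2. Adjusted over the list alone, 1 was higher with edgeR, against 0 over all genes tested with edgeR and 1 higher with DESeq2. The TGF-beta and BMP response (adjusted p = 0.493) had Ccn1 at -0.71, Tgfbi at 0.68 and Bmp6 at 0.35. Choroid plexus genes (0.259) had Igf2 at 0.77 and Kl at 0.29 (0.17 without knockout replicate 2), and Ttr was 39.1 CPM in wildtype replicate 1 and at most 5.71 CPM in the other libraries. The interferon response, blood, ependyma, thalamus, striatum, microglia, endothelium, mural cells, oligodendrocyte precursors, heat shock genes and ribosomal proteins did not pass either, with camera adjusted p between 0.259 and 0.887.

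The folds followed base composition across genes. The 3455 genes of lowest GC content (median 42.2%) had a median log2 fold of 0.06 and the 3454 of highest GC content (median 57.3%) one of -0.07. With offsets for GC content and transcript length, chosen after the data were seen, 7 lists passed, and the mitochondrial list did not (mean 0.14, adjusted p = 0.149).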

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

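The share of each file's total placed at several sites, which no gene test uses, was higher in every knockout library than in every wildtype library. It was 21.8% ± 0.71 in knockout and 20.7% ± 0.41 in wildtype (SD, n = 3). An exact two-sided permutation test gave p = 0.1, the smallest that 3 libraries against 3 can give. No explanation was tested.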

How the results depend on the processing

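The alternatives on GC and length, thinning, bias-adjusted deviances, depth set and chromosome 17 were chosen after the data were seen. Counts of genes depended on the tool and filter. Without a filter edgeR called 62 genes (36 higher, 26 lower), DESeq2 163 (70 and 93), the robust fit 15 (13 and 2) and an adjusted p of 0.10 gave 18 (14 and 4). All other settings with every library called 0. Leaving out 1 library gave 0 to 17 genes (0 to 13 higher, 0 to 7 lower): 17 without knockout replicate 3, 16 without wildtype replicate 2, and 2 without wildtype replicate 1 or knockout replicate 1. The number of lists was 0 with an estimated correlation and 0 with fry's directional test, where the glucocorticoid mean of 0.13 had adjusted p of 0.421 and 0.280. It was 6 to 11 without 1 library and 6 to 9 otherwise. Seed sets passing were 0 in every setting run. The cause was not tested.

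The replicate numbers pair nothing. A fit with the replicate number as a block called 0 genes and 9 lists, the added one being choroid plexus (adjusted p = 0.0432). Deviations of same-numbered libraries correlated at -0.10, -0.02 and -0.15 across genes, and no library correlated best with its own number.

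Directions that turned belonged to results that did not pass. Leaving out 1 library moved the host fold between -0.49 and 0.041, newborn neurons between -0.069 and 0.038, neural stem cells between -0.057 and 0.012, anxiety and depression between -0.011 and 0.055, choroid plexus between -0.038 and 0.24, Mki67 between -0.22 and 0.061, Nes between -0.18 and 0.12, Sgk3 between -0.12 and 0.080, Ttr between -2.48 and 0.060, the miR-17 set between -0.0036 and 0.0103 and the miR-18 set between -0.0046 and 0.0025. Newborn neurons turned to 0.0010 with a filter of 1 CPM, and choroid plexus to -0.12 with that filter and -0.10 with none. Nes turned to 0.045 with GC and length offsets and 0.0094 with thinning. Seed sets turned for miR-17 to -0.0073 without a filter, for miR-18 to 7.3e-05 with limma-voom, 0.0032 with GC and length offsets and 0.0073 with 8mer sites, for miR-92 to -0.0096 with 8mer sites, and for miR-17, miR-19 and miR-92 to -0.0016, -0.0026 and -0.00038 as residuals on UTR length and GC. With the depth set as a covariate 6 lists passed, and oligodendrocytes (adjusted p = 0.0763) and cortex (0.120) did not. Another scaling moved the median fold by at most 0.004. Without a turn, leaving out 1 library moved cluster targets between -0.032 and -0.00086, the miR-19 set between 0.0015 and 0.011 and the miR-92 set between 0.0073 and 0.019. With GC and length offsets the log2 folds of Ccne2, Elavl2, Bdnf, mt-Nd2, mt-Nd4, mt-Nd1 and Pcp4 were 0.15, 0.04, 0.11, 0.14, 0.07, 0.12 and 0.09. Among named genes, none of which passed in the main test, 86 values under other settings did.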

Other observations

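Tests here of cell content and of the chromosome 17 window against chance positions were chosen after the results were seen. So were those without H2 genes under offsets and for the fullest window of that chromosome without H2 genes. Tests of the targeted locus, of the deeper and shallower libraries, and of splits by unadjusted p were also chosen then. Genes of chromosome 17 and those listed per library were chosen after their values were seen.

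Higher glucocorticoid and astrocyte genes with lower immediate early genes form the first pattern. GC content and transcript length do not account for it, since all 3 lists passed with offsets for both (3 of 3, camera adjusted p of 8.67e-08, 1.17e-14 and 3.13e-11), though 0 passed with an estimated correlation. The glucocorticoid mean log2 fold was 0.13 for the genotypes and 0.15 in the highest of the other 9 splits (wildtype 1, wildtype 3 and knockout 2 against the rest). The 67 genes of the neuron lists had a median log2 fold of 0.03, so they did not fall as a set. Its bootstrap SE of 0.03 is across genes, not mice. In list level, knockout minus wildtype was 0.12 for dentate, 0.008 for CA1, -0.001 for CA2 and CA3 and -0.02 for interneurons. For these genes, the lack of a fall argues against fewer neurons as the source of the lower immediate early genes. The test chosen for this question, on the gap between both medians, could not tell. The neuron lists' median lay 0.28 above the immediate early median, with a standard error of 0.16 that leaves the size of this gap uncertain. More astrocytes as a source of the higher glucocorticoid genes stay open, with the astrocyte median at -0.043 from theirs (SE 0.06). Handling or stress before dissection, which may also move both lists, was not tested.

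Genes of small p lay together on chromosome 17, with 12 of the 67 genes at p under 0.001 (one-sided hypergeometric adjusted p = 0.00116). The fullest window of 50 neighbours ran from Vars to H2-Bl and held 10 genes at p under 0.01, 4 higher and 6 lower, among them Aif1 (log2 fold 0.88), H2-D1, H2-T24 and Gpank1 (-0.56), with a permutation p of 0.004. With GC and length offsets the fullest window was another on chromosome 17, from H2-T24 to Capn11, with 12 genes. Its permutation p was 1e-04, the smallest the permutations can give. GC content and length therefore do not account for all such gathering on that chromosome. The window from Vars to H2-Bl itself was not tested again. Reads shared among histocompatibility genes may account for part. Without H2 genes, 5 of the 10, the fullest window of all lay on chromosome 10 (permutation p = 0.1525). The fullest on chromosome 17 then ran from Zdhhc14 to Thbs2 and held 7 genes. Its permutation p was 0.5863 against the fullest window anywhere after shuffling. Leaving out H2 genes lowers the count by itself. With offsets and without H2 genes a window from Ppp1r11 to Dlk2 on the same chromosome still held 8 genes (permutation p = 0.0045). That window does not rest on counts of H2 genes. Genes were left out by the name H2 alone, so reads shared with relatives under other names are not excluded. A stretch of another strain's chromosome carried with the knockout is a candidate explanation (permutation p = 0.004), found and tested on the same data, and the fullest window of the other 9 splits held up to 14 genes, on chromosome 4 between the deeper and shallower libraries.

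The split of the libraries that parts the 3 deeper from the 3 shallower ones called 30 genes with edgeR, against 0 for the genotypes, which points to a structure of the samples, although it gave fewer genes at an unadjusted p under 0.05 (883 against 1746) and with DESeq2 (83 against 163). Vcp was 24.9, 26.4 and 24.7 CPM in wildtype 1, wildtype 2 and knockout 3 and 43.3, 44.3 and 41.1 CPM in wildtype 3, knockout 1 and knockout 2, while its processed pseudogene Vcp-rs was 19.3, 19.96 and 20.4 CPM and 0.945, 0.836 and 0.794 CPM in the same order. Reads placed differently between copies in 2 sequencing or alignment runs may account for part, as 20% of the called genes and 1.98% of the others were pseudogenes (Fisher's exact p = 2.48e-05). With offsets and without named copies a window from Uqcrq to Trim17 on chromosome 11 held 9 genes (permutation p = 3e-04). GC content, length and the counts of named copies therefore do not account for all of it. Genes whose copies lie elsewhere stayed in that test, so reads placed differently between copies are not excluded. Strain segments that differ between mice are untested beyond that window, and the labels give no run or batch.

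Some libraries also stood apart in a few genes. Cwc22 was 435 CPM in wildtype 2 and 124 CPM in wildtype 3, against 12.9 to 15.1 CPM in the other 4 libraries. Glo1, which lies on chromosome 17, was 91.2 CPM in wildtype 2 and 44.4 to 47.1 CPM elsewhere. Wildtype libraries thus also differed among themselves in a gene of that chromosome. Trim12a had 0 CPM in wildtype 3 and knockout 1 and 1.10 to 1.33 CPM in the others.

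Loss of repression by the cluster's microRNAs, if it reaches most cells of the tissue, predicts higher levels of genes with seed sites. With UTR length and GC as covariates, the 4 seeds lay at percentiles 5.70, 49.4, 31.5 and 10.02 of motifs with shuffled bases, so none lay in the upper tail that had been set before the result was seen. Near the targeted locus 1 of the 50 nearest tested genes was at p under 0.01, where 1.46 were expected (exact hypergeometric p = 0.773), too few to exclude a kept stretch.

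The 10 splits of 6 libraries are too few for a share under 0.05. The genotypes gave 1746 genes at an unadjusted p under 0.05 and the highest other split 1151, so 1 split reached the real number. For lists the real number was 8 and the highest other 9, with 3 splits at 8 or more. For seed sets it was 0 in all 10.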
